A study of Bacillus subtilis subsp. subtilis NCIB 3610 = ATCC 6051 = DSM 10 with 15 samples.

How the data were processed

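Bacillus subtilis NCIB 3610 cells were profiled by RNA sequencing in 5 groups, which the labels name. Cells kept for 4 h in MSgg, a defined medium used for biofilm studies, were the untreated group, and cells moved to MSgg with secretions of Arabidopsis roots were the treated group. Root-associated cells were grown from an OD of 0.02 in MSgg with seedlings 7 d old, so this group also differed from the others in how it was started. The last 2 groups were descendants regrown in LB, a rich medium, from untreated and from secretion-treated cells. Per the labels, RNA came from lysozyme and TRIzol with a DNase step, rRNA was depleted with Ribo-Zero, and no polyA capture was used.

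The deposited values were integer read counts per gene, made by the authors with cutadapt, Bowtie2 2.3.4.1, HTSeq and DESeq2 1.16, per the labels. The genome build, the strandedness and the counting options are not given in the sources used here, so no coordinates are printed. The count table held 4466 features in 14 libraries of the 15 that the labels list. Replicate 3 of the LB descendants of secretion-treated cells had no column and was not analysed here, so that group had 2 libraries and each other group had 3. LB descendants of untreated replicate 1 is named untreated in its title and secretion-treated in its treatment field, and the title was followed. The labels do not say whether replicates were separate cultures. Replicates were not treated as pairs in the main fit. Residual correlations between libraries of the same number ran from -0.22 to 0.199. Libraries of unlike number were not compared in this way, so these values cannot tell whether the numbers mark pairs.

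Counts were used as deposited. edgeR 4.0.16 in R 4.3.3 was run with TMM factors and filterByExpr by group, which kept 3773 features for testing and left out 693. One quasi-likelihood model with 1 mean per group was fitted to all 14 libraries. Adjusted p values of genes are Benjamini-Hochberg values from edgeR's quasi-likelihood test over the 3773 features, with a threshold of 0.05. Fold changes are on the log2 scale with their standard errors (SE), and levels are CPM, counts scaled to the effective library size after TMM, as mean and standard deviation (SD). Genes with no count in a group were given only a lower bound, taken against a floor of 3 counts over the group. Genes with 1 to 3 counts in a group were given a ratio with its 95% exact interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

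Gene lists, the rule for named genes, comparisons and most of the other settings tried were chosen before the data were examined. The lists were 44 sets of operons and regulons written from textbook knowledge of this species, with 906 memberships, of which 888 matched a symbol of the table and 828 were tested. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 44 lists, and with fry and with camera at an estimated correlation as alternatives. fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Named genes were the largest changes of each comparison, up to 10 higher and 10 lower, among genes past the threshold with a mean log2 CPM of at least 3, groups that did not overlap and a symbol. At most 2 of them per direction shared their first 3 letters. Up to 4 members with the smallest p of each list described were added. So were 12 markers, whether or not they passed: epsA, tapA, tasA, bslA, hag, sigD, srfAA, spo0A, sigB, comK, katA and dhbA. Features without a symbol, 233 in number, and 30 rRNA features were not named.

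The test was checked on simulated counts with the depths of these libraries and a spread per gene that all groups shared. In the comparison of secretions with MSgg it recovered 78% of genes changed by 2 on the log2 scale and 7% of those changed by 1, with 6 false calls among 91. For the descendants it recovered 64% and 9%, with 3 false calls among 76. Groups of unequal spread were not simulated, while the biological coefficient of variation of the real groups ran from 15.4% to 43.6%. Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, other scaling factors, other low-count filters, no structural RNA, the replicate number as a block, only the 2 groups compared, a fold threshold and each library left out in turn. A count after thinning all libraries to the smallest, and one with the library of conflicting labels counted as secretion-treated, were added after seeing the data.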

Results

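Transcripts were counted in 14 libraries of Bacillus subtilis NCIB 3610 from 5 groups. The MSgg untreated, MSgg with secretions, root-associated and LB descendants of untreated groups had 3 libraries each, and the LB descendants of secretion-treated group had 2. Total counts ran from 742393 to 1073908 in the untreated group and from 2545969 to 4234313 with secretions. Root-associated libraries held 1600793 to 1762250 counts, descendants of untreated cells 1449803 to 2981142, and descendants of treated cells 1943741 to 1966019. A single count stood for 0.222 CPM in the deepest library and 1.51 CPM in the shallowest, so low transcripts were measured least well in untreated cells. rRNA took 22.9% ± 2.33 of counts (SD, n = 3) in untreated cells, 10.8% ± 1.99 (SD, n = 3) with secretions and 11.3% ± 1.57 (SD, n = 3) in root-associated cells. In the descendants its share was 9.02% ± 2.6 (SD, n = 3) after untreated and 9.54% ± 2.44 (SD, n = 2) after treated cells. The biological coefficient of variation was 40.2% in the untreated group, 25.5% with secretions, 30.8% on roots, 43.6% in descendants of untreated and 15.4% in descendants of treated cells. Scaling by library totals alone moved the median log2 change of all genes, from 0.16 to 0.41 for secretions, from 0.05 to 0.38 for roots and from -0.07 to -0.20 for the descendants. Changes below are relative to the TMM scale unless stated.

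**Figure D1:**
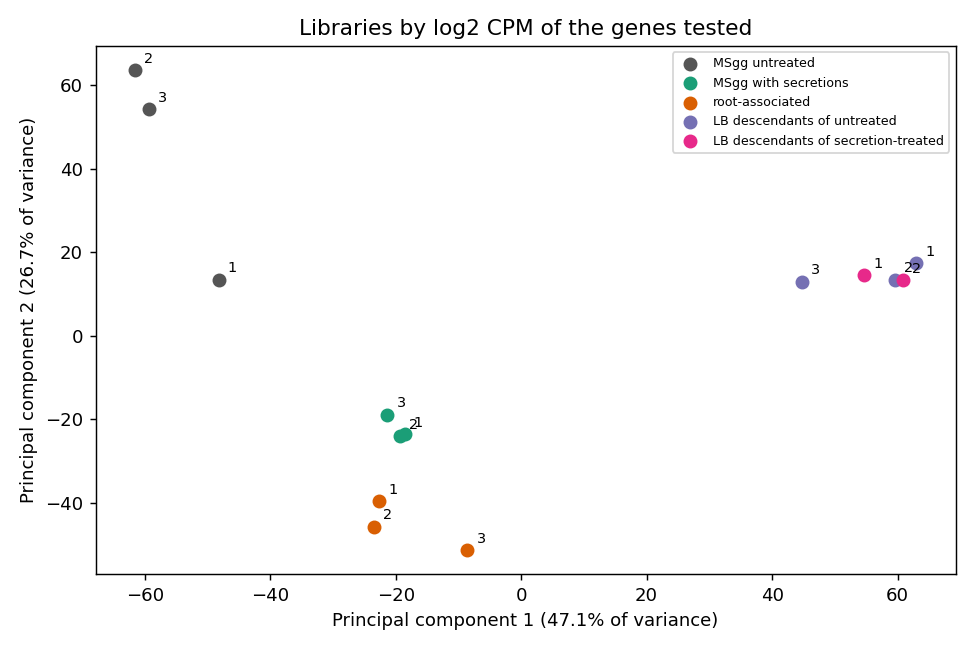
Principal components of log2 CPM of the 14 libraries, each point a library coloured by group and numbered by replicate, with 47.1% of the variance on the first axis and 26.7% on the second. MSgg untreated replicate 1 lies apart from the rest of its group. On the plotted axes LB descendants of untreated replicate 3 and root-associated replicate 3 lie apart from theirs by less. On the third axis, not plotted and with 10.2% of the variance, LB descendants of untreated replicate 3 stands at 51.19. The others of its group stand at -5.877 and 6.756 there.

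Cells given root secretions carried more transcript of the biofilm matrix and of iron-scavenging siderophore synthesis than untreated cells, and less of the peroxide and DNA damage responses. tasA (BS3610_RS14205), which encodes the main fibre protein of the matrix, averaged 179.5 CPM ± 20.0 (SD, n = 3) with secretions and 7.53 CPM ± 9.42 (SD, n = 3) without, a log2 change of 4.40 ± 0.88 (SE, adjusted p = 0.00249). dhbF (BS3610_RS18145), a peptide synthetase of the siderophore bacillibactin, averaged 2856 CPM ± 351 against 182.7 CPM ± 172 (SD, n = 3 each), a log2 change of 3.96 ± 0.58 (SE, adjusted p = 0.000355). katA (BS3610_RS05750), the vegetative catalase, fell from 4225 CPM ± 2140 to 211.5 CPM ± 109 (SD, n = 3 each), a log2 change of -4.32 ± 0.54 (SE, adjusted p = 0.000151). dinB (BS3610_RS03970), induced by DNA damage, averaged 83.2 CPM ± 16.2 against 1682 CPM ± 656 (SD, n = 3 each), a log2 change of -4.34 ± 0.39 (SE, adjusted p = 1.43e-05). The question was what secretions change, but the labels give 4 h in MSgg for the untreated cells and no time for the treated ones, so time of exposure was not separated from secretions.

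Of the 19 measured genes of the biofilm matrix list, 15 rose, 0 fell and 4 did not pass, and 18 rose when adjusted over the list alone. bslA, the hydrophobic coat protein of the biofilm, changed by 4.35 ± 0.55 on the log2 scale (SE, adjusted p = 0.000151), from few reads in untreated cells. epsI, an exopolysaccharide gene without a count in untreated cells, was at least 8.51-fold higher. The list median was 2.79, or 2.75 with such genes at their bound (camera adjusted p = 7.31e-06, and adjusted p = 0.859 with an estimated correlation). In the siderophore and iron uptake list 25 of 29 genes rose and 1 fell, the same counts as adjusted over the list alone. Besides dhbF, dhbC changed by 4.08 ± 0.68 and fhuC, of ferrichrome import, by 3.13 ± 0.57 on the log2 scale. The list median was 2.71 (camera adjusted p = 6.23e-08, and adjusted p = 0.859 with an estimated correlation). Of 27 genes for the antibiotics bacillaene, plipastatin and bacilysin, 19 rose and 1 fell, and 21 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.15e-05, and adjusted p = 0.859 with an estimated correlation). pksL changed by 2.99 ± 0.64, ppsD by 3.08 ± 0.69 and pksA, the exception, by -1.41 ± 0.29 on the log2 scale. All 4 surfactin genes measured rose, also when adjusted over the list alone, with srfAB at 2.17 ± 0.41 (camera adjusted p = 0.027, and adjusted p = 0.859 with an estimated correlation). One of them, srfAA, rose by 1.42 ± 0.40 on the log2 scale, but without MSgg untreated replicate 2 its adjusted p was 0.0549.

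In the flagellum and motility list 25 of 40 genes rose and 5 fell, with 25 and 6 when adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.859 with an estimated correlation). fliZ, of flagellar export, changed by 3.30 ± 0.51 and the motility sigma factor gene sigD by 1.37 ± 0.30, while swrAA, which promotes swarming, changed by -2.33 ± 0.38 on the log2 scale. The flagellin gene hag did not pass, at -0.75 ± 0.39 (SE, adjusted p = 0.131). Inositol and ribose use rose in 16 of 20 genes with 0 lower, and in 17 when adjusted over the list alone. iolD changed by 2.93 ± 0.70 on the log2 scale, and the list median was 2.26, or 2.07 with 1 gene at its bound (camera adjusted p = 8.61e-05, and adjusted p = 0.859 with an estimated correlation). Of 20 genes of the ATP synthase and cytochrome oxidases 16 rose and 1 fell, the same when adjusted over the list alone, with atpA at 2.34 ± 0.45 (camera adjusted p = 9.38e-05, and adjusted p = 0.859 with an estimated correlation). Of 32 genes of the general stress sigma factor SigB 13 rose and 0 fell, as they did when adjusted over the list alone, with the catalase gene katE at 1.69 ± 0.40 (camera adjusted p = 0.00326, and adjusted p = 0.859 with an estimated correlation).

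Lower transcripts included 8 of 12 genes of the peroxide response, with 2 higher, and 9 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.00238, and adjusted p = 0.859 with an estimated correlation). zosA, a metal transport ATPase, changed by -5.06 ± 0.55 and the repressor gene perR by -2.38 ± 0.39 on the log2 scale. The higher 2, hemB at 1.41 ± 0.35 and hemL at 1.36 ± 0.33, encode heme synthesis enzymes, and they were picked out after their values were seen. Of 12 genes of the SOS response to DNA damage 8 fell and 0 rose, the same when adjusted over the list alone (camera adjusted p = 0.00041, and adjusted p = 0.859 with an estimated correlation). yneA, a division inhibitor, changed by -3.32 ± 0.48 and lexA, the SOS repressor gene, by -1.61 ± 0.31 on the log2 scale. The steepest fall among named genes was in yocH, a cell wall hydrolase gene, at -6.86 ± 0.55 (SE, adjusted p = 1.34e-05), from 11950 CPM ± 4240 to 102.9 CPM ± 38.6 (SD, n = 3 each). The arsenic resistance genes arsB and arsC changed by -5.98 ± 0.71 and -6.05 ± 0.72. The rRNA share moved with all of these groups, at 22.9% in untreated cells against 10.8% with secretions. MSgg untreated replicate 1 correlated at 0.899 and 0.922 with the other 2 untreated libraries, which correlated at 0.954. With the 3 secretion libraries replicate 1 correlated at 0.905, 0.904 and 0.916, about as closely as with its own group. The other 2 untreated libraries correlated with the secretion libraries at 0.741 to 0.819. Without untreated replicate 1 edgeR called 1762 genes.

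edgeR's test called 1525 of 3773 genes between secretions and MSgg, 826 higher and 699 lower. This balance depended on the scaling, with 1076 higher and 506 lower under library totals, 752 and 763 under RLE factors, and 681 and 838 under upper-quartile factors. It also turned without rRNA and tRNA, to 706 higher and 782 lower, and under DESeq2, to 814 and 818. A fit of only the 2 groups gave 691 and 772, and leaving out MSgg untreated replicate 2 gave 417 and 463. The 2 groups did not overlap in 57.9% of genes, where chance gives 10%. Without MSgg untreated replicate 2 the count was 880. At the preset correlation 10 of 44 lists shifted, at an estimated one 0 did (lowest adjusted p = 0.859), fry called 10, and a mixed split of the same 6 libraries gave 14.

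Root-associated cells carried more transcript of the biofilm matrix, siderophore synthesis and ribosomal proteins than untreated cells, and less of envelope stress genes, the peroxide response and the arsenite efflux gene arsB. bslA averaged 118.6 CPM ± 28.9 (SD, n = 3) on roots and 2.28 CPM ± 2.01 (SD, n = 3) in untreated cells, a log2 change of 5.55 ± 0.54 (SE, adjusted p = 1.17e-05). A single count stood for 0.952 to 1.51 CPM in the untreated libraries, so the untreated level of bslA rests on few reads and the size of its change is uncertain. dhbF averaged 10400 CPM ± 4050 against 182.7 CPM ± 172 (SD, n = 3 each), a log2 change of 5.82 ± 0.63 (SE, adjusted p = 2.72e-05). arsB averaged 3.87 CPM ± 1.25 against 1980 CPM ± 1350 (SD, n = 3 each), a log2 change of -8.99 ± 0.83 (SE, adjusted p = 9.67e-06). gapB, the glyceraldehyde phosphate dehydrogenase of gluconeogenesis, averaged 49.3 CPM ± 29.7 against 3963 CPM ± 731 (SD, n = 3 each), a log2 change of -6.33 ± 1.01 (SE, adjusted p = 0.000263). The comparison asks what growth with seedlings changes, but these cells were also started and grown differently.

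In the matrix list 18 of 19 genes rose and 0 fell, the same when adjusted over the list alone, with a median of 4.16, or 4.07 with genes at their bound (camera adjusted p = 4.12e-07, and adjusted p = 0.676 with an estimated correlation). tasA changed by 5.11 ± 0.90 and epsD by 4.40 ± 0.73 on the log2 scale, and epsI was at least 25.2-fold higher. Siderophore and iron uptake genes rose in 25 of 29 with 0 lower, and 25 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.9e-09, and adjusted p = 0.676 with an estimated correlation). Of the bacillaene, plipastatin and bacilysin genes 24 of 27 rose and 1 fell, and 25 rose and 1 fell when adjusted over the list alone, with pksJ at 4.50 ± 0.72 (camera adjusted p = 4.12e-07, and adjusted p = 0.676 with an estimated correlation). The 4 surfactin genes rose again, also when adjusted over the list alone, with srfAB at 3.31 ± 0.43 (camera adjusted p = 0.00632, and adjusted p = 0.676 with an estimated correlation). Among 24 genes for cannibalism toxins and bacteriocins 18 rose and 3 fell, and 20 rose and 3 fell when adjusted over the list alone. albG, of subtilosin export, changed by 2.83 ± 0.55 and sdpI, an immunity gene, by -1.72 ± 0.27 (camera adjusted p = 0.00411, and adjusted p = 0.676 with an estimated correlation). Type VII secretion rose in 7 of 11 genes with 0 lower, the same when adjusted over the list alone, with yukE at 1.94 ± 0.45 (camera adjusted p = 0.0258, and adjusted p = 0.676 with an estimated correlation). In the flagellum list 25 of 40 rose and 6 fell, the same when adjusted over the list alone, with flhA at 4.02 ± 0.48 (camera adjusted p = 0.000833, and adjusted p = 0.676 with an estimated correlation). The flagellin gene hag was lower, at 1.47% to 2.93% of counts on roots against 2.55% to 5.26% in untreated cells (edgeR adjusted p = 0.0326). Its call was lost without 4 of the 6 libraries in turn.

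Branched-chain amino acid synthesis rose in 7 of 9 genes with 0 lower, the same when adjusted over the list alone, with ilvC at 3.86 ± 0.66 and leuB at 4.12 ± 0.71 (camera adjusted p = 0.00411, and adjusted p = 0.676 with an estimated correlation). In arginine synthesis 8 of 9 rose and 0 fell, and 9 rose when adjusted over the list alone, with argD at 2.04 ± 0.53 (camera adjusted p = 0.0121, and adjusted p = 0.676 with an estimated correlation). Of 49 ribosomal protein genes 29 rose and 3 fell, and 30 and 4 when adjusted over the list alone, with rpsC at 3.94 ± 0.58 (camera adjusted p = 0.000171, and adjusted p = 0.792 with an estimated correlation). Glycolysis rose in 12 of 17 genes and fell in 1, and in 14 and 2 when adjusted over the list alone, with pfkA, phosphofructokinase, at 1.99 ± 0.32 (camera adjusted p = 0.00399, and adjusted p = 0.676 with an estimated correlation). Of the 20 ATP synthase and oxidase genes 9 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.00492, and adjusted p = 0.676 with an estimated correlation). SigB genes rose in 12 of 32 and fell in 1, and 10 rose when adjusted over the list alone, with sigB at 1.95 ± 0.39 (camera adjusted p = 0.011, and adjusted p = 0.792 with an estimated correlation).

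Envelope stress genes of SigW and LiaRS fell in 18 of 25 with 0 higher, and 19 fell when adjusted over the list alone (camera adjusted p = 4.12e-07, and adjusted p = 0.676 with an estimated correlation). sigW, the sigma factor gene itself, changed by -4.02 ± 0.50 and fosB, for fosfomycin resistance, by -3.35 ± 0.44 on the log2 scale. Peroxide response genes fell in 8 of 12 and rose in 2, the same when adjusted over the list alone, with katA at -5.90 ± 0.59 (camera adjusted p = 0.00411, and adjusted p = 0.676 with an estimated correlation). In the SOS response 7 of 12 fell and 0 rose, and 7 fell and 1 rose when adjusted over the list alone, with dinB at -5.19 ± 0.40 (camera adjusted p = 0.00411, and adjusted p = 0.676 with an estimated correlation). Of 55 genes for plant polysaccharides 16 fell and 4 rose, and 14 and 3 when adjusted over the list alone. The pectate lyase gene pel, at 3.45 ± 0.34, rose, and araE, an arabinose carrier gene, changed by -3.71 ± 0.54 (camera adjusted p = 0.0258, and adjusted p = 0.792 with an estimated correlation). Sulfur and methionine genes fell in 12 of 31 and rose in 1, the same when adjusted over the list alone, with mccB at -3.68 ± 0.52 (camera adjusted p = 0.00199, and adjusted p = 0.676 with an estimated correlation). In the nitrogen limitation list 8 of 21 fell and 1 rose, the same when adjusted over the list alone, with the regulator gene tnrA at -3.46 ± 0.49 (camera adjusted p = 0.0334, and adjusted p = 0.792 with an estimated correlation). The rRNA share moved with these groups as well, at 22.9% in untreated cells against 11.3% on roots.

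The edgeR test called 1867 genes between roots and MSgg, 1003 higher and 864 lower. This balance depended on the scaling too, with 1271 higher and 609 lower under library totals, 951 and 921 under RLE factors, and 898 and 968, the other way round, under upper-quartile factors. The groups did not overlap in 58.1% of genes, where chance gives 10%. At the preset correlation 19 lists shifted, at an estimated one 0 did (lowest adjusted p = 0.676), fry called 22, and a mixed split of the 6 libraries gave 18.

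**Figure D2:**
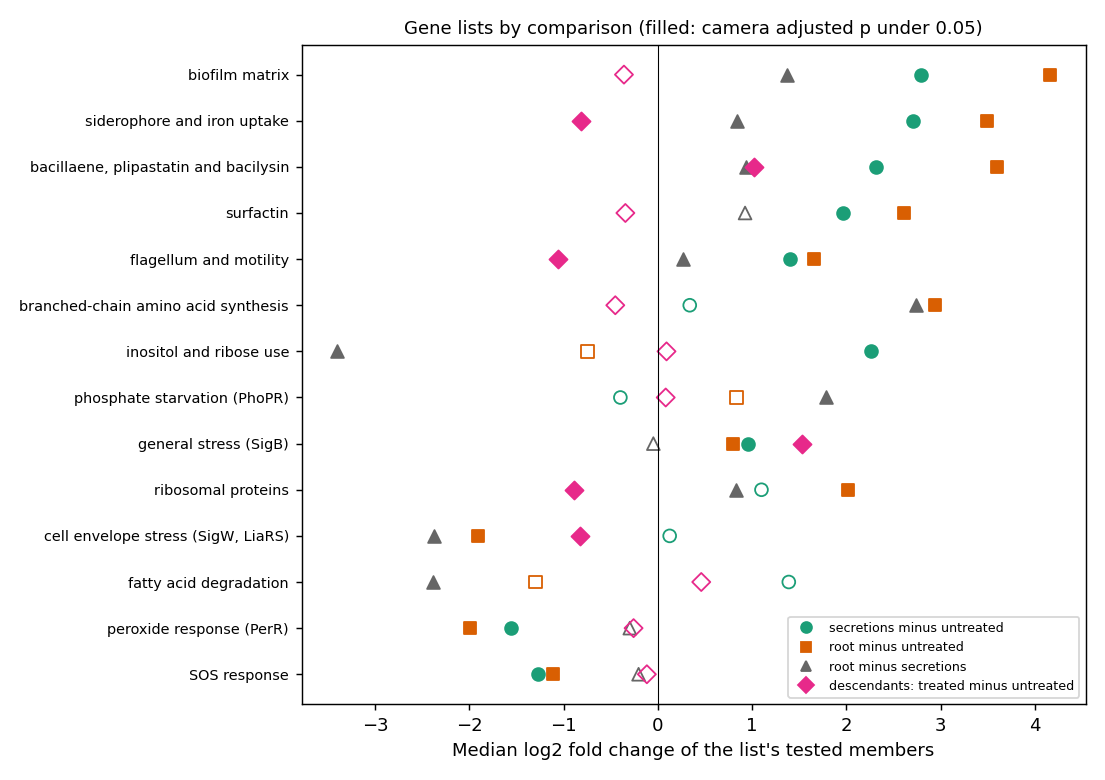
Median log2 fold change of 14 gene lists in each of the 4 comparisons, with filled symbols for lists that passed camera at the preset correlation and open symbols for those that did not. The biofilm matrix list stood at 2.79 with secretions and 4.16 on roots.

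Root-associated cells carried more transcript of phosphate uptake and leucine synthesis than cells given secretions, and less of inositol use and envelope stress genes and of pckA. pstC (BS3610_RS14390), of the high-affinity phosphate importer, averaged 163.6 CPM ± 146 on roots and 6.56 CPM ± 1.59 with secretions (SD, n = 3 each), a log2 change of 4.61 ± 0.63 (SE, adjusted p = 0.000706). leuB (BS3610_RS16120), of leucine synthesis, averaged 2241 CPM ± 1240 against 227.5 CPM ± 145 (SD, n = 3 each), a log2 change of 3.30 ± 0.68 (SE, adjusted p = 0.00687). pckA, the phosphoenolpyruvate carboxykinase of gluconeogenesis, averaged 90.6 CPM ± 16.9 against 3574 CPM ± 1420 (SD, n = 3 each), a log2 change of -5.30 ± 0.72 (SE, adjusted p = 0.000706). iolT, an inositol carrier gene, averaged 5.97 CPM ± 4.60 against 128.8 CPM ± 51.7 (SD, n = 3 each), a log2 change of -4.46 ± 0.54 (SE, adjusted p = 0.000609). The list of glycerol use and gluconeogenesis that holds pckA did not shift, with 1 of 12 genes higher and 2 lower (camera adjusted p = 0.748). The question was how root association differs from secretions alone, but root-associated cells were also started and grown differently, which was not separated from it.

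Phosphate starvation genes rose in 9 of 17 with 0 lower, and 9 rose and 1 fell when adjusted over the list alone, with pstA, another importer gene, at 4.33 ± 0.56 (camera adjusted p = 2.33e-05, and adjusted p = 0.573 with an estimated correlation). Branched-chain amino acid synthesis rose in 7 of 9, also when adjusted over the list alone, with leuA at 2.84 ± 0.48 (camera adjusted p = 2.69e-06, and adjusted p = 0.573 with an estimated correlation). Of 49 ribosomal protein genes 10 rose and 0 fell, and 11 rose when adjusted over the list alone, with rpsJ at 1.74 ± 0.37 (camera adjusted p = 1.1e-07, and adjusted p = 0.573 with an estimated correlation). The matrix list rose in 3 of 19 genes, and in 10 when adjusted over the list alone (camera adjusted p = 0.00419, and adjusted p = 0.573 with an estimated correlation). tasA did not pass, at 0.71 ± 0.69 (SE, adjusted p = 0.551), and its value turned to -0.32 under limma voom and to -0.48 without root-associated replicate 3. Siderophore genes rose in 5 of 29, and in 7 when adjusted over the list alone (camera adjusted p = 9e-05, and adjusted p = 0.573 with an estimated correlation).

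Envelope stress genes fell in 15 of 25, and in 19 when adjusted over the list alone, with fosB at -3.20 ± 0.43 and yvlC at -2.65 ± 0.34 (camera adjusted p = 5.32e-19, and adjusted p = 0.204 with an estimated correlation). Inositol and ribose genes fell in 16 of 20, also when adjusted over the list alone, with iolB at -4.56 ± 0.68 (camera adjusted p = 7.78e-15, and adjusted p = 0.555 with an estimated correlation). Fatty acid degradation fell in 10 of 11, also when adjusted over the list alone, with lcfB, an acyl-CoA ligase gene, at -2.19 ± 0.41 (camera adjusted p = 4.15e-08, and adjusted p = 0.573 with an estimated correlation). Plant polysaccharide genes fell in 15 of 55 and rose in 1, and 19 fell and 2 rose when adjusted over the list alone, with the arabinanase gene abnA at -4.17 ± 0.74 (camera adjusted p = 2.24e-07, and adjusted p = 0.573 with an estimated correlation). For sucrose, levan and beta-glucoside use 9 of 21 fell and 0 rose, also when adjusted over the list alone, with bglH at -3.93 ± 0.48 (camera adjusted p = 0.00016, and adjusted p = 0.573 with an estimated correlation). In sulfur and methionine synthesis 7 of 31 fell and 1 rose, and 14 and 1 when adjusted over the list alone, with mccB at -2.91 ± 0.50 (camera adjusted p = 0.00166, and adjusted p = 0.573 with an estimated correlation). In the tricarboxylic acid cycle list of 13 genes 2 fell, citZ at -2.03 ± 0.42 and citB at -1.62 ± 0.44, also when adjusted over the list alone (camera adjusted p = 0.00195, and adjusted p = 0.573 with an estimated correlation). Nitrogen limitation genes fell in 7 of 21, and in 9 when adjusted over the list alone (camera adjusted p = 0.0225, and adjusted p = 0.573 with an estimated correlation).

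The other lists higher on roots than with secretions had few genes past the threshold, and each had an adjusted p = 0.573 with an estimated correlation. Counts adjusted over the list alone stand second in each pair here. Flagellar genes rose in 5 and 5 of 40 (camera adjusted p = 0.0342), antibiotic synthesis genes in 2 and 6 of 27 (camera adjusted p = 0.00166) and cannibalism and bacteriocin genes in 5 and 7 of 24, with 0 and 1 lower (camera adjusted p = 0.0477). Type VII secretion rose in 3 and 3 of 11 (camera adjusted p = 0.00195), glycolysis in 2 and 2 of 17 (camera adjusted p = 0.00302), arginine synthesis in 2 and 2 of 9 (camera adjusted p = 0.0102) and anaerobic respiration in 3 and 3 of 21 (camera adjusted p = 0.0061). The nitrate carrier gene narK stood at 1.81 ± 0.38 on the log2 scale (SE, adjusted p = 0.00765).

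edgeR called 454 genes between roots and secretions, 188 higher and 266 lower, and 201 and 227 under library totals, 195 and 263 under RLE factors and 209 and 261 under upper-quartile factors. The balance turned to 256 higher and 244 lower without rRNA and tRNA and to 461 and 458 under limma voom, and stood at 60 and 172 without MSgg with secretions replicate 1. The groups did not overlap in 40.4% of genes, where chance gives 10%. The count was 232 without MSgg with secretions replicate 1 or 3, 278 without its replicate 2, and 256 and 265 without root-associated replicate 2 and 3, against 919 under limma voom and 753 in a fit of only the 2 groups. The genes printed with a value here, apart from tasA and citB, passed without each of the 6 libraries in turn. At the preset correlation 20 lists shifted, at an estimated one 0 did (lowest adjusted p = 0.204), fry called 6, and a mixed split gave 21.

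**Figure D3:**
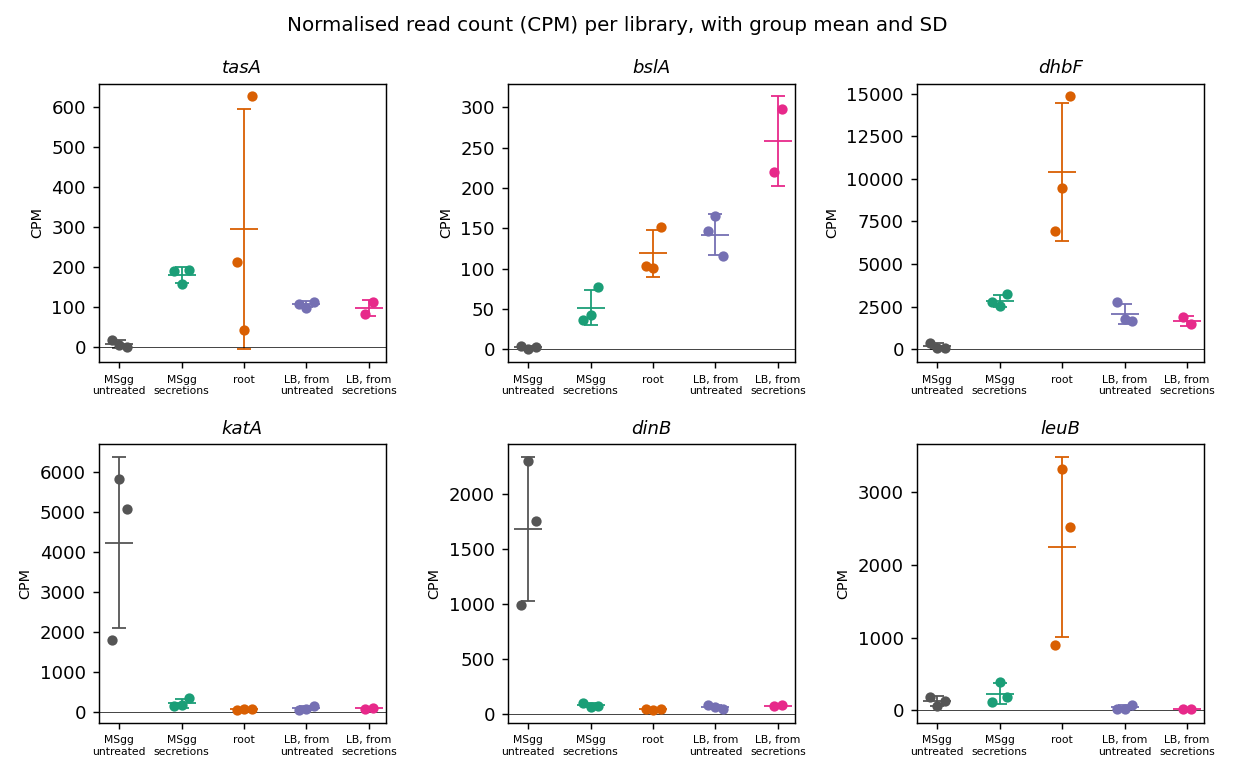
CPM of tasA, bslA, dhbF, katA, dinB and leuB in each library of the 5 groups on linear axes, with points for libraries, horizontal lines for group means and error bars for the SD. tasA averaged 179.5 CPM with secretions, 294.2 CPM on roots and 7.53 CPM in untreated cells.

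Secretion-exposed and root-associated cells shared most of their changes against untreated cells. Of the genes higher with secretions 624 were also higher on roots, where independent calls would give 220, and 563 were lower in both, where they would give 160, while 15 went opposite ways. Fold changes correlated across genes at r = 0.802, and genes are not independent replicates. Both comparisons use the same 3 untreated libraries, which cannot be divided between them. In 20 simulations of unchanged groups against shared controls r averaged 0.595 with a highest value of 0.628 and covariance averaged 0.21, against 1.77 in the data. All simulated groups had the spread of the untreated libraries (40.2%), wider than that with secretions (25.5%) or on roots (30.8%). Narrower groups would raise the simulated r, so 0.628 is not its upper limit.

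Descendants of secretion-treated cells carried more transcript of gsiB, mntC and aprE than descendants of untreated cells after regrowth in LB, and less of ptsG. Without LB descendants of secretion-treated replicate 1, gsiB, aprE and ptsG lost their call (adjusted p = 0.0865, 0.11 and 0.239), while mntC passed without any 1 of the 5 libraries. In an edgeR fit of only these 5 libraries 0 genes passed, so mntC was not called there either. gsiB (BS3610_RS03255), a general stress gene, averaged 6134 CPM ± 1570 (SD, n = 2) against 605.1 CPM ± 442 (SD, n = 3), a log2 change of 3.34 ± 0.49 (SE, adjusted p = 0.00406). mntC (BS3610_RS17385), of the manganese importer, averaged 297.1 CPM ± 166 (SD, n = 2) against 43.7 CPM ± 13.5 (SD, n = 3), a log2 change of 2.75 ± 0.38 (SE, adjusted p = 0.00405). aprE, the subtilisin gene, averaged 1550 CPM ± 34.0 (SD, n = 2) against 136.7 CPM ± 132 (SD, n = 3), a log2 change of 3.51 ± 0.65 (SE, adjusted p = 0.00948). ptsG, the glucose carrier gene, averaged 140.8 CPM ± 18.6 (SD, n = 2) against 1898 CPM ± 1420 (SD, n = 3), a log2 change of -3.75 ± 0.69 (SE, adjusted p = 0.00948). The comparison asks whether exposure left a trace in cells regrown in LB.

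SigB genes rose in 10 of 32 with 0 lower, and in 28 when adjusted over the list alone, with ysnF at 3.17 ± 0.47 and csbD at 2.21 ± 0.45 (camera adjusted p = 1.37e-23, and adjusted p = 0.467 with an estimated correlation). Of 16 genes for arginine, proline and histidine use 2 rose and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 1.56e-09, and adjusted p = 0.487 with an estimated correlation). These were the amino acid permease genes rocC at 2.47 ± 0.53 and rocE at 1.89 ± 0.46. The acetoin dehydrogenase genes acoA and acoB rose by 3.43 ± 0.62 and 3.44 ± 0.62 on the log2 scale. Osmoprotection rose in 2 of 17 genes, opuE at 1.70 ± 0.34 and opuBC at 1.83 ± 0.47, and in 4 when adjusted over the list alone (camera adjusted p = 0.0222, and adjusted p = 0.487 with an estimated correlation). Its median was 0.13 and turned to -0.01 under library totals.

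Flagellar genes fell in 2 of 40, ylxH at -1.77 ± 0.39 and flhF at -1.86 ± 0.47, and in 22 when adjusted over the list alone (camera adjusted p = 7.39e-12, and adjusted p = 0.413 with an estimated correlation). Chemotaxis genes passed in 0 of 18 over all genes, and 17 fell when adjusted over the list alone, with a list median of -1.22 (camera adjusted p = 2.16e-09, and adjusted p = 0.231 with an estimated correlation). Glycolysis fell in 5 of 17, and in 6 when adjusted over the list alone, among them gapA at -1.95 ± 0.48 (camera adjusted p = 1.7e-07, and adjusted p = 0.487 with an estimated correlation). Pyrimidine synthesis passed in 0 of 10 over all genes, and 9 fell when adjusted over the list alone, with a list median of -2.46 (camera adjusted p = 6.31e-05, and adjusted p = 0.487 with an estimated correlation). Ribosomal protein genes passed in 0 of 49, also when adjusted over the list alone, with a median of -0.89 (camera adjusted p = 1.74e-05, and adjusted p = 0.825 with an estimated correlation). The matrix genes tasA at -0.12 ± 0.78 (SE, adjusted p = 0.954) and bslA at 0.86 ± 0.39 (SE, adjusted p = 0.23) did not pass. The sign of tasA turned to 0.08 without LB descendants of secretion-treated replicate 1.

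The other shifted lists had 0 or 1 gene past the threshold over all genes. Extracellular proteases rose in 1 of 8, aprE, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.487 with an estimated correlation). Type VII secretion passed in 0 of 11, and 2 rose when adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.487 with an estimated correlation), and anaerobic respiration in 0 of 21, where 2 fell when adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.591 with an estimated correlation). In 4 lists 0 genes passed, also when adjusted over the list alone. Antibiotic synthesis had a median of 1.02 (camera adjusted p = 3.6e-05, and adjusted p = 0.743 with an estimated correlation) and plant polysaccharide use of 0.80 (camera adjusted p = 1.06e-06, and adjusted p = 0.487 with an estimated correlation). Siderophore and iron uptake had a median of -0.82 (camera adjusted p = 0.00109, and adjusted p = 0.836 with an estimated correlation), as had envelope stress (camera adjusted p = 0.000149, and adjusted p = 0.487 with an estimated correlation).

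**Figure D4:**
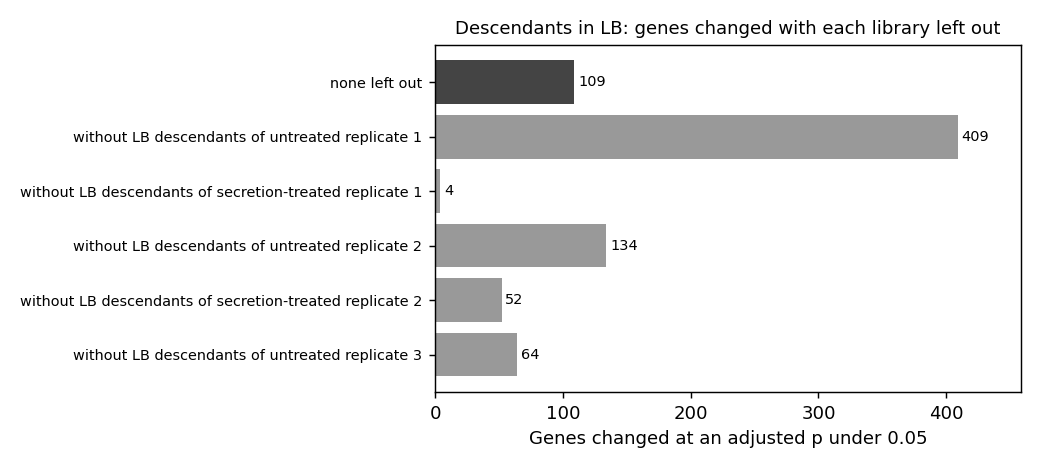
Number of genes called by edgeR between the LB descendants of secretion-treated and of untreated cells, with all 5 libraries (dark bar) and with each library left out in turn (light bars). The count was 109 with all libraries and ran from 4 to 409 without single ones.

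edgeR called 109 genes in the descendants, 88 higher and 21 lower, with 73 and 31 under library totals, 90 and 23 under RLE factors and 95 and 24 under upper-quartile factors. The groups did not overlap in 39% of genes, where chance gives 20%. Single libraries decided this count, which was 4 without LB descendants of secretion-treated replicate 1, 52 without its replicate 2, 64 without LB descendants of untreated replicate 3 and 409 without its replicate 1. DESeq2 called 306, limma voom 629, edgeR with the replicate block 37, 33 higher and 4 lower, and an edgeR fit of only these 5 libraries 0 (530 at an unadjusted p under 0.05). With the library of conflicting labels counted as secretion-treated edgeR called 267, and the balance turned to 132 higher and 135 lower. Those 267 held 34 of the 109 genes. Of 29 named genes that passed, mntC and mntD passed without each of the 5 libraries. At the preset correlation 15 lists shifted, at an estimated one 0 did (lowest adjusted p = 0.231), and fry called 3. No mixed splits were run for the descendants. In the other comparisons mixed splits shifted up to 14, 18 and 21 lists at the preset correlation. Lists that stay shifted without 1 library are therefore not shown to follow the earlier exposure. LB descendants of untreated replicate 3 correlated at 0.888 and 0.935 with the other 2 libraries of its group, which correlated at 0.968. Without it 13 of the 15 lists still shifted, and type VII secretion (camera adjusted p = 0.079) and ribosomal proteins (camera adjusted p = 0.139) did not. Without each other library 14 of the 15 did. The list lost was osmoprotection without LB descendants of untreated replicate 1 (camera adjusted p = 0.133) and anaerobic respiration without its replicate 2 (camera adjusted p = 0.0526). It was anaerobic respiration without LB descendants of secretion-treated replicate 1 (camera adjusted p = 0.0544) and type VII secretion without its replicate 2 (camera adjusted p = 0.17).

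The matrix gene bslA and the catalase gene katA, which moved with secretions in MSgg, did not pass in the descendants, and mntC moved the opposite way. The difference was tested gene by gene and for no list. bslA rose by 4.35 ± 0.55 in treated cells and stood at 0.86 ± 0.39 in descendants, a difference of -3.49 ± 0.71 (SE, adjusted p = 0.00708). katA stood at -4.32 ± 0.54 and -0.12 ± 0.54, a difference of 4.2 ± 0.73 (SE, adjusted p = 0.00377). mntC fell with secretions and rose in descendants, from -2.80 ± 0.41 to 2.75 ± 0.38, a difference of 5.55 ± 0.56 (SE, adjusted p = 9.39e-05). The rule for named genes picked mntC only in the descendants, so its fall with secretions and this difference were looked up afterwards. It was not called between the descendants in a fit of only their libraries, where 0 genes passed.

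edgeR's test of the difference called 626 genes, 279 higher and 347 lower. This balance depended on the scaling, with 162 higher and 557 lower under library totals, 322 and 327 under RLE factors, and 357 and 307, the other way round, under upper-quartile factors. It also turned to 67 higher and 37 lower without LB descendants of secretion-treated replicate 1, to 136 and 90 without its replicate 2. Without LB descendants of untreated replicate 1 it was 374 and 372, and without its replicate 2 it was 246 and 240. The count was 104 and 226 without LB descendants of secretion-treated replicate 1 and 2, 1087, 372 and 357 without MSgg untreated replicate 1, 2 and 3, and 1593 under limma voom. Fold changes of the 2 effects correlated across genes at r = 0.116. Of 88 genes higher in descendants 30 were also higher with secretions, where 19.3 would be so by independent calls (Fisher's exact test, two-sided, p = 0.00849), and of 21 lower 5 were also lower, against 3.89 (Fisher's exact test, two-sided, p = 0.571), while 16 went opposite ways. Genes are not independent replicates in these tests.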

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

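The tests of depth, of single untreated libraries, of scaling, of rRNA counts, of a wrong label and of 1 descendant library alone were chosen only after the results were seen, and the counts over other splits were planned.

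The effect of secretions in MSgg and the difference between the descendants were compared with a test of the difference itself, which called 626 genes. Of these, 536 were called with secretions in MSgg, 46 in the descendants and 17 in both. Several genes that rose with secretions did not pass in the descendants, with differences on the log2 scale of -5.46 for dhbC (adjusted p = 0.00442), -5.20 for dhbA (adjusted p = 0.00738), -4.52 for tasA (adjusted p = 0.0227), -4.48 for flhA (adjusted p = 0.00189), -4.17 for tapA (adjusted p = 0.0292), -3.49 for bslA (adjusted p = 0.00708) and -2.98 for epsA (adjusted p = 0.0315). sigD differed by -2.37 (adjusted p = 0.00529) and katA, which fell with secretions, by 4.2 (adjusted p = 0.00377). In MSgg the effects were 2.62 for flhA, 4.08 for dhbC and 3.90 for dhbA, and in the descendants -1.86, -1.38 and -1.31, none of which passed (adjusted p = 0.0561, 0.272 and 0.343). With secretions, 3 of 3 libraries lay beyond all untreated libraries for each of the genes named here. Groups of 3 or fewer libraries were not tested for single libraries far from the rest.

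Many genes of the peroxide and SOS responses were lower both with secretions and on roots than in untreated cells. With secretions 8 of 12 genes of each list fell, and on roots 8 peroxide and 7 SOS genes fell. In each comparison 2 peroxide genes rose instead. Camera at an estimated correlation shifted 0 lists in either comparison (lowest adjusted p = 0.859 and 0.676). The falls made 31 calls over both lists and comparisons. Shallower untreated libraries are argued against as the whole cause, since 96.8% of these calls were still made after all libraries were thinned to the smallest. A single untreated library is argued against too, as at least 87.1% were still called without any 1 of the 3. Scaling is argued against as the whole cause, since at least 83.9% were still called under library totals, RLE or upper-quartile factors, with 26 of the 31 under library totals. Without rRNA and tRNA 100% were still called. TMM factors already offset most of the share taken by rRNA, and the median log2 change for secretions moved only from 0.16 to 0.03. That result could hardly have come out otherwise, so it does not decide whether the rRNA difference plays a part. A response of untreated cells to their 4 h in MSgg may underlie the difference and was not tested.

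The difference between the descendant groups may rest on a single library. The labels of LB descendants of untreated replicate 1 conflict, and without that library 99.1% of the 109 called genes (108) were still called. Their median absolute log2 change was 2.06, against 2.04 with all libraries, so these calls did not need that library. Whether its label is wrong cannot be told this way, since a treated library counted as untreated would shrink the difference. Leaving it out raised the count to 409. Counted as secretion-treated, it gave 267 genes, which held 34 of the 109. On the 409 genes called without it, it lay at a median of 0.599 between the other untreated (0) and the treated descendants (1), with quartiles of 0.34 and 0.82, and a position in the middle leaves its label open. These genes were picked for their difference from the other untreated libraries, which by itself can place a library left out nearer the treated side. Over all genes tested it correlated at 0.968 and 0.888 with the other untreated descendants and at 0.955 and 0.965 with the treated ones. Without any 1 of the 5 libraries at least 99.1% of the called genes kept their direction and at least 50% of their log2 fold change, yet 4 were still called without LB descendants of secretion-treated replicate 1, 51 without its replicate 2 and 58 without LB descendants of untreated replicate 3. The median absolute log2 change was 1.76, 2.21 and 1.72 without each of these in turn. An effect of the earlier exposure stays open and was not tested apart from these.

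Splits of the same 6 libraries into other groups of 3 cannot give a share under 0.05, as there are 10. The descendants were not split in this way. For genes, 1 split of 10 reached the real count in each comparison, with 1525 for secretions, 1867 for roots and 454 for roots against secretions, and the highest other count was 0 each time (edgeR's test, with 1891, 2111 and 1040 genes at an unadjusted p under 0.05 in the real splits). For lists at the preset correlation, 7 of 10 splits reached the real count of 10 for secretions (highest other 14), 1 reached 19 for roots (highest other 18) and 2 reached 20 for roots against secretions (highest other 21).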

How the results depend on the processing

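The thinning and the other label of 1 library were chosen after seeing the data, and the rest was planned. The counts of genes stayed within 1.5 times under other scaling factors, low-count filters, a fold threshold, no structural RNA and thinning (1346, 1683, 364, 91 and 528 genes for secretions, roots, roots against secretions, descendants and the difference of effects). DESeq2 gave 306 in the descendants, and limma voom 919 for roots against secretions, 629 in the descendants and 1593 for the difference. With the replicate block the descendants gave 37, and with only the 2 groups compared roots against secretions gave 753 and the descendants 0 (edgeR, 530 at an unadjusted p under 0.05). Camera with an estimated correlation called 0 lists in each comparison, where fry called 10, 22, 6 and 3, of which 6 for roots against secretions and 3 for the descendants were fewer than at the preset correlation. The conflicting library counted as secretion-treated gave 267 genes, which held 34 of the 109 called in the main fit. The cause was not tested for any of these. Leaving out each library gave 880–1762 genes for secretions, 232–323 for roots against secretions, 4–409 for the descendants and 104–1087 for the difference, with the lowest without MSgg untreated replicate 2, MSgg with secretions replicate 1 or 3, and, for the last 2, LB descendants of secretion-treated replicate 1. A group left with 1 library was assumed to vary like the others. The correlation of fold changes ran over 0.775–0.873 for secretions and roots (0.873 without MSgg untreated replicate 1) and 0.0283–0.16 for secretions and descendants (0.0283 without LB descendants of untreated replicate 3).

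Values of named genes that changed sign were not called before or after. For roots against secretions tasA moved to -0.32 under limma voom and -0.48 without root-associated replicate 3 (range without single libraries -0.48 to 1.23). In the descendants katA moved to 0.14 under limma voom, 0.23 with the replicate block, 0.077 without LB descendants of secretion-treated replicate 1 and 0.35 without LB descendants of untreated replicate 3 (range -0.41 to 0.35), and tasA to 0.13 with the replicate block and 0.075 without LB descendants of secretion-treated replicate 1 (range -0.35 to 0.075). spo0A moved to 0.059 without LB descendants of untreated replicate 2 (range -0.21 to 0.059), 0.022 with the other label and 0.032 after thinning, tapA to 0.039 and srfAA to 0.033 with the other label. Of the values of named genes, 1111 of 1152 for secretions, 2010 of 2037 for roots, 1508 of 1742 for roots against secretions and 1177 of 1454 for the descendants kept direction and side of the threshold. Depth limited low transcripts, since 1 count stood for up to 1.51 CPM.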

Other observations

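Several manganese and copper genes were lower in both MSgg comparisons, and no list of such genes was tested. The rule for named genes picked mntC in the descendants only. Its values in MSgg and the other genes in this paragraph were chosen after the values were seen. The manganese importer genes mntA, mntB and mntC fell with secretions, with mntA at -2.77 ± 0.51, mntB at -3.33 ± 0.61 and mntC at -2.80 ± 0.41 on the log2 scale (SE, adjusted p = 0.00151, 0.00148 and 0.000355), as did mntR, the regulator gene, at -2.30 ± 0.35 (adjusted p = 0.00043), with 3 of 3 libraries below all untreated ones for each. On roots mntA stood at -3.33 ± 0.58 and mntC at -2.86 ± 0.43 (adjusted p = 0.000432 and 0.000183). The copper genes copA, an efflux ATPase, and copZ, a chaperone, stood at -2.89 and -3.46 on the log2 scale with secretions and at -3.70 and -4.00 on roots (adjusted p = 0.00148, 0.000379, 0.000176 and 8.54e-05). csoR, the copper repressor gene, stood at -0.04 ± 0.25 with secretions (adjusted p = 0.921). In the descendants mntB stood at 2.70 ± 0.47 (adjusted p = 0.00948), higher in 2 of 2 libraries than in all 3 of the other group, and mntA at 1.56 ± 0.41 did not pass (adjusted p = 0.0574).

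Of the 44 lists, 14 passed camera in no comparison, and the lowest adjusted p among them was 0.0644, for autolysins and cell separation. Early sporulation had medians of 1.41 with secretions and 1.43 on roots, with 4 and 5 of 15 genes higher and 1 lower in each. Competence had 2 of 15 genes higher and 3 lower with secretions. Its regulator gene comK stood at 0.68 ± 0.32 with secretions (adjusted p = 0.104) and rose by 1.34 ± 0.32 on roots (adjusted p = 0.00367). The sporulation regulator gene spo0A did not pass in either, at 0.36 ± 0.26 and -0.41 ± 0.26 (adjusted p = 0.283 and 0.199).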
